A study of Mus musculus with 2 samples.

How the data were processed

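Dissociated cells of newborn mouse tooth germs (mandibular molars, C57BL/6 background) were profiled by single-cell RNA sequencing on the BD Rhapsody microwell system. In the control, Edar carries loxP sites (floxed) and no Cre is present. In the other group the K14cre transgene, active in keratin 14-expressing epithelium, is added to the same floxed allele. Each group was 1 library, so 2 libraries were compared. The number and sexes of the germs in a library are not given in the sources used here. Cells with Xist, a transcript of female cells, and no Y-linked UMI were 20.8% of kept control and 34.9% of kept deletion cells. The reverse held for 38.7% and 24.1%, and only 1.65% and 2.35% held both. Each library therefore held cells of both sexes, from more than 1 pup.

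The values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, deposited by the authors with no normalization. Per the submitters' processing notes, STARsolo and the mm10 build were used. The STARsolo version, the annotation and the rule by which barcodes were kept are not given in the sources used here. The smallest barcode in each library held 500 UMIs. Of 31253 features, 31184 had an identifier in the GENCODE M21 annotation of mm10, and 30273 of them had the same symbol there. Another 48 features repeated a symbol and were kept apart by identifier. Gene positions come from that annotation.

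The control library held 13990 barcodes and 73375441 UMIs, and the deletion library 16029 barcodes and 62158879 UMIs. Barcodes with at least 500 detected genes and at most 20% mitochondrial UMIs passed, which were 13431 and 15487. Too few genes removed 266 and 233 barcodes, and a high mitochondrial share 366 and 360, with some barcodes failing both. Scrublet, as built into scanpy, was run on each library with a fixed seed and called 178 doublets (1.33%) in the control and 240 (1.55%) in the deletion library, which were removed. The 13253 and 15247 kept cells had medians of 4444 and 3329 UMIs and of 1932 and 1616 genes.

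Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the library as batch, leaving out mitochondrial, ribosomal protein, haemoglobin and sex-linked genes. Next came 30 principal components, 15 neighbours and Leiden clustering at resolution 1. Epithelium-like and mesenchyme-like cells were clustered again at resolution 0.6. A cluster took the name whose markers it expressed most relative to other clusters. At least 3 of those markers had to be detected in 25% of its cells, with a lead of at least 0.1 in score over the next name, and a closer call was settled only where its top 10 genes by fold held at least 2 markers of a tied name and more than of the next. It stayed unnamed where these top genes held more markers of another class, or where its cells were very shallow and none of its own markers stood among them. The markers were fixed before the data were examined, and the scoring rule afterwards. A named subtype's share was compared only where none of the 10 leading genes of its sub-clusters passed the 2-fold rule within it, a condition also set afterwards.

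For each class, UMIs were summed per library and expressed as CPM, the count of a gene scaled to the same class total in both libraries. With 1 library per group no test across animals exists, so no p-value was computed. A gene counted as higher or lower when it had at least 50 CPM in 1 library, when (CPM + 5) differed at least 2-fold and when the 95% conditional binomial interval of the count ratio excluded 1. Log2 ratios are on the scale of CPM + 5, deletion over control, which understates differences of weakly expressed genes. Levels carry exact Poisson intervals and shares exact Clopper-Pearson intervals, and list medians and log2 ratios carry intervals from 1000 Poisson resamplings. An interval of a difference between shares runs between opposite ends of their intervals, so it is wider than a 95% interval. All other intervals are at 95%, and all cover counting error only, not the variation between animals or dissociations.

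A list was summarised by its median log2 ratio over members with at least 5 CPM in either library. It was placed by percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The lists covered EDAR pathway members, EDAR and NF-kB targets, enamel knot signals, enamel matrix, stratum intermedium and stellate reticulum, and the Hedgehog, Wnt, BMP and TGF-beta, FGF and Notch pathways. Others covered dentin, dental transcription factors, dental follicle, keratins, adhesion, collagens and matrix, S phase, G2 and M phase, immediate early genes, hypoxia and glycolysis, interferon response, and apoptosis and p53. The rest were osteoclast-directed signals and vessels, and sex-linked, haemoglobin, ribosomal protein and mitochondrial genes.

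The rule of size, the lists, the other settings given at the end and the rule for named genes were chosen before the data were examined. In the epithelium-like and mesenchyme-like classes the rule named up to 12 genes with the largest and 12 with the smallest ratio among those counted. In other classes with at least 100 cells per library it named 3 each way. It left out mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin and T cell receptor genes and unnamed gene models. It also left out genes over 10 times higher in another class with at least 50 cells of the same library, as these can come from free RNA. This removed 3 of 8 counted genes in epithelium (Xist, Col3a1 and Zfp36) and 1 of 22 in mesenchyme (Xist).

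For shares of cells with a UMI and for cycling cells, each cell was thinned to 1900 UMIs, which left out 946 shallower control cells and 1644 deletion cells. A cell with at least 2 UMIs of the G2 and M phase list after thinning counted as cycling.

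The rule of size and the list median were tested on simulated counts, with gene means from the whole libraries and totals close to those of each class. At each fold size 50 genes were altered, all of them well above the minimum level. For epithelium-like totals, with 3458 genes tested, 0% of 1.5-fold, 28% of 2-fold, 100% of 3-fold and 100% of 4-fold differences were called. For mesenchyme-like totals, with 3400 genes tested, the shares were 0%, 50%, 100% and 100%. Of the unaltered genes at the minimum level, 0 of 3238 and 0 of 3180 were called. The simulation held counting error only, so 0 calls say nothing of variation between animals, dissociations or the makeup of a class. A list shifted by 0.5 in log2 had a median of 0.45 and 0.38. A true difference near 2-fold was therefore often missed.

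The other settings chosen in advance were stricter cell filters (1000 genes and 10% mitochondrial UMIs), no doublet removal, resolution 2, clustering of each library on its own, class names from markers per cell, thinned cells, median-of-ratios scaling, a pseudocount of 1 CPM and no minimum level. Settings added after the data were seen are named where their values are given. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9 were used.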

Results

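Mutations of the ectodysplasin pathway cause hypohidrotic ectodermal dysplasia, in which teeth, hair and sweat glands form abnormally. Edar is the receptor of ectodysplasin in the epithelium of these organs. The study asked how loss of Edar in epithelium alone alters the tooth germ. Newborn molar germs of floxed control mice and of mice with K14cre-driven Edar deletion were compared, with 1 library in each group. The control library held 73375441 UMIs and the deletion library 62158879, and kept cells had medians of 4444 and 3329 UMIs. There was no replicate check for any difference below. Counts of genes follow a rule of size in these 2 libraries, and all intervals cover counting error only.

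Edar was lower in the epithelium-like cells of the deletion library. Edar (ENSMUSG00000003227, minus strand of chromosome 10, positions 58600789 to 58675654 of mm10) stood at 34.6 CPM in control epithelium-like cells (interval 31.1 to 38.3, 360 UMIs) and at 21.2 CPM in the deletion library (17.8 to 24.9, 145 UMIs). The log2 ratio was -0.60, and the count ratio lay between 0.50 and 0.74. Levels were highest in enamel knot-like cells, the signalling centre of the tooth germ, with 242 CPM in the control and 175 CPM in the deletion library. Inner enamel epithelium-like cells, the precursors of ameloblasts, had 40.6 and 24.2 CPM. Oral keratinocyte-like cells had 27.5 CPM (20 UMIs) and 12.8 CPM (8 UMIs), and stratum intermedium-like cells 12.6 CPM (10 UMIs) and 6.63 CPM (4 UMIs). Ameloblast-like cells had 2.85 and 3.13 CPM (4 and 2 UMIs), and stellate reticulum-like cells 5 and 0 UMIs. In mesenchyme-like cells Edar stood at 1.08 and 1.07 CPM. In endothelium-like cells it had 2 and 3 UMIs, in macrophage-like cells 2 and 1, in mural-like cells 2 and 0, in neutrophil-like cells 1 and 0, in osteoclast-like cells 0 and 1, and in glia-like and lymphocyte-like cells 0 in both libraries. The unnamed clusters together held 16 and 21 UMIs (6.43 CPM, interval 3.67 to 10.4, and 3.92 CPM, 2.42 to 5.99), above the 0.41 and 0.83 CPM of endothelium-like cells.

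An Edar UMI was found in 10.5% of control epithelium-like cells and in 5.94% of those with the deletion, at median depths of 3991 and 3008 UMIs. After thinning to 1900 UMIs, which left out 946 control and 1644 deletion cells over all classes, the shares were 6.0% and 4.42%. Endothelium-like cells, which should lack Edar, gave 0.16% and 0.30% at median depths of 3022 and 2963 UMIs, and 0.10% and 0.13% after thinning. In thinned epithelium-like cells the log2 ratio of Edar was -0.33, with an interval from -0.69 to 0.01 that includes 0. The tags of this assay lie at the 3' end of transcripts and may be outside the deleted part of the gene, so the remaining level may check nothing.

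**Figure D1:**
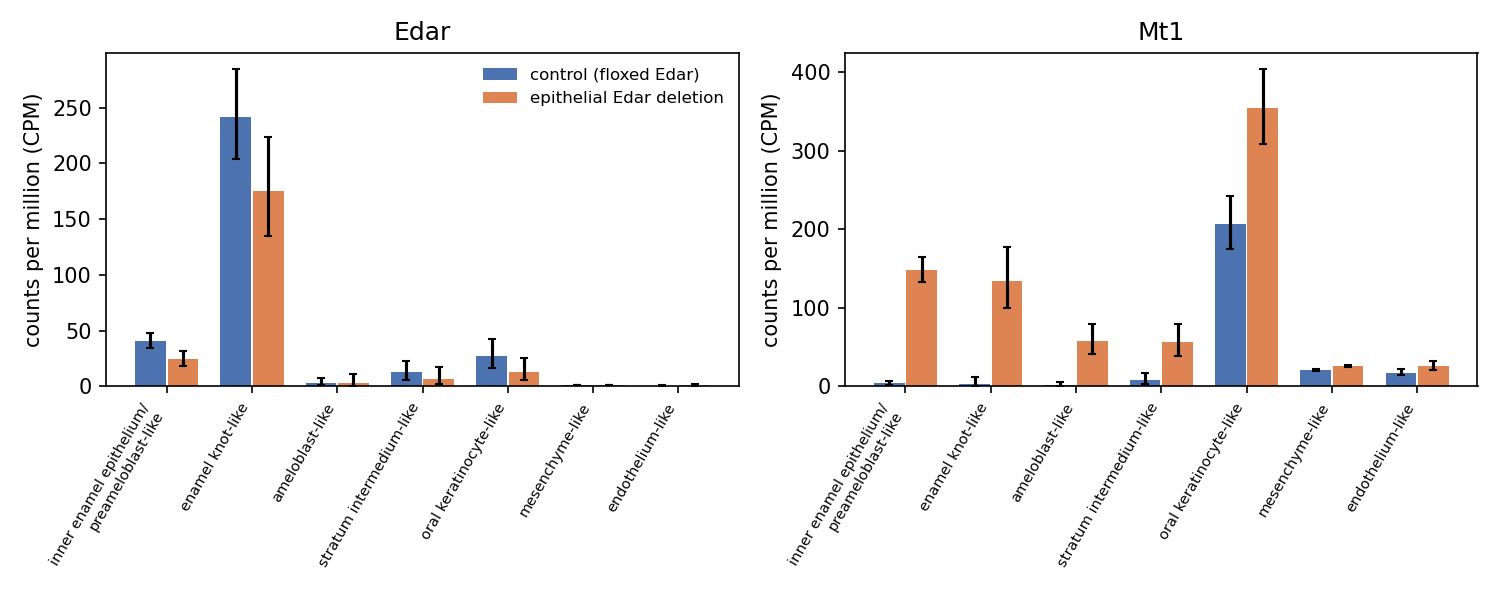
CPM of Edar (left) and Mt1 (right) in epithelial subtypes, mesenchyme-like and endothelium-like cells of the control (blue) and Edar deletion (orange) library, with exact 95% Poisson intervals as error bars. Edar was highest in enamel knot-like cells (242 and 175 CPM), and Mt1 in inner enamel epithelium-like cells stood at 3.67 and 148 CPM.

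Over all kept cells, epithelium-like cells made up a smaller part of the deletion library. Mesenchyme-like cells made up a larger one, by a margin that depended on unnamed cluster 5. The epithelium-like share was 17.2% of kept cells in the control (2275 cells, interval 16.5 to 17.8%) and 12.4% in the deletion library (1887 cells, 11.9 to 12.9%), a difference of -4.79 percentage points. Mesenchyme-like cells were 60.3% and 62.9%, a difference of 2.63 points (1.03 to 4.24). With cluster 5 added, an alternative chosen after the data were seen, they were 64.0% and 72.1%, a difference of 8.15 points (6.61 to 9.68). Endothelium-like cells were 9.26% and 6.45%, macrophage-like cells 4.08% and 3.31%, and mural-like cells 2.75% and 2.31%. Neutrophil-like cells were 1.03% and 0.89%, glia-like cells 0.29% and 0.71%, osteoclast-like cells 0.31% and 0.68%, and lymphocyte-like cells 0.17% and 0.24%. Cluster 5, which stayed unnamed and was led by Rspo4, Vit, Col8a2 and Col9a2, took 3.68% and 9.20%, and cluster 18, which mixed mast and myeloid markers, 0.96% and 0.91%. Within epithelium, ameloblast-like cells, which secrete enamel proteins, were 13.6% (interval 12.2 to 15.1%) and 9.27% (8.0 to 10.7%). Inner enamel epithelium-like cells were 34.0% and 31.5%, stratum intermedium-like cells 8.04% and 7.95%, and stellate reticulum-like cells 2.90% and 1.59%. Unnamed sub-cluster 6, led by Col3a1 and Postn, took 8.35% and 16.6% of the class, but 1 of its 10 leading genes itself differed 2-fold. Enzymatic digestion, sieving, red-cell lysis, dead-cell removal, the gap in depth and the mix of sexes can each set such shares. Of cells with Xist, made in female cells, and no Y-linked UMI, 386 of 2760 and 880 of 5320 were epithelium-like. That share was not lower in the deletion library. Of epithelium-like cells with Xist or Y-linked UMIs only, 386 of 1269 and 880 of 1168 held Xist. Of such ameloblast-like cells 44 of 191 and 79 of 126 did. Their share of the class was therefore about alike among cells with Y-linked UMIs only, and lower among those with Xist only.

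Few genes in epithelium differed 2-fold, and the metallothionein gene Mt1 stood out. Of 3555 genes at the minimum level, 6 were higher and 2 lower in the deletion library. Those higher numbered 2 with equal sub-cluster weights, and those lower 5 under a stricter cell filter, 4 with a pseudocount of 1 CPM and 11 with no minimum level. Mt1, which binds zinc and copper (chromosome 8, 94179082 to 94180327), stood at 24.5 CPM in the control (interval 21.6 to 27.7) and 156 CPM in the deletion library (147 to 166), a count ratio between 5.56 and 7.34. The heat shock gene Hspa1a had 42.9 and 95.3 CPM, and Fos, a transcription factor switched on within minutes of stimulation, 499 and 1015 CPM. Hspa1a has a near-identical copy in Hspa1b, so its counts are uncertain. Idi2, an isoprenoid enzyme gene, had 80.8 and 12.1 CPM, and Calm4, a calmodulin-like gene of keratinocytes, 71.4 and 26.7 CPM. Both of these lead the oral keratinocyte-like sub-cluster, and without it their log2 ratios turned to 0.10 and 0.27. That sub-cluster was not a smaller part of the class (7.16% and 10.4%), but 5 of its 10 leading genes, Krt4, Idi2, Calm4, Serpinb3a and Sprr3, were 2-fold lower within it, so its share is not compared. The X inactivation transcript Xist, made in female cells, had 178 and 503 CPM in epithelium. Past 1.5-fold, 17 genes were higher and 14 lower.

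Mt1 was higher in every named epithelial subtype of the deletion library. In inner enamel epithelium-like cells it had 14 and 348 UMIs (3.67 and 148 CPM), in enamel knot-like cells 3.36 and 134 CPM, in ameloblast-like cells 1.42 and 57.9 CPM and in stratum intermedium-like cells 7.53 and 56.4 CPM. Oral keratinocyte-like cells had 206 and 354 CPM, and stellate reticulum-like cells 94.9 and 326 CPM. Mesenchyme-like cells had 20.8 and 25.9 CPM, endothelium-like cells 17.5 and 26.3 CPM, and macrophage-like cells 671 and 575 CPM. The related gene Mt2 had 66.9 and 90.7 CPM in epithelium, and 42.3 and 83.0 CPM in mesenchyme.

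The enamel knot and enamel matrix lists had medians slightly below 0 in epithelium, while the interval of EDAR targets included 0. None of the members of these 3 lists passed the 2-fold rule. Of 13 measured enamel knot signals, 10 had log2 ratios below 0, 7 of them with a count interval below 1. Edar, the targeted gene, is itself a member of this list and is among those 7. The list's median was -0.32 (interval -0.44 to -0.20, percentile 0.00 among matched lists). Shh, the Hedgehog ligand of dental epithelium, had 494 and 351 CPM, Wnt10b 41.8 and 23.5 CPM, and the cell cycle inhibitor Cdkn1a 222 and 152 CPM. Of 19 enamel genes, 17 lay below 0, 12 of them with a count interval below 1, and the median was -0.23 (-0.27 to -0.11, percentile 0.00). Odam had 157 and 96.9 CPM, the transcription factor genes Dlx3 and Msx2 367 and 235 CPM and 360 and 230 CPM, and the main enamel matrix gene Amelx 6310 and 5906 CPM. Amelx turned to 0.06 without sub-clusters led by mesenchymal genes and to 0.35 with equal sub-cluster weights. With those weights the enamel median was -0.11, and within ameloblast-like cells it was -0.01 (-0.19 to 0.17). Both lists were also lower in mesenchyme-like cells, with medians of -0.39 and -0.33, although Amelx itself had 22.1 and 47.1 CPM there. EDAR and NF-kB targets had a median of -0.06 (-0.17 to 0.04, percentile 33.4), with 6 of 15 above 0. Nfkbia, an inhibitor and target of NF-kB, had 149 and 165 CPM, and Sostdc1, a BMP and Wnt antagonist, 524 and 498 CPM. The 14 measured EDAR pathway members had a median of -0.02, and the adaptor Edaradd had 87.5 and 96.4 CPM.

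Hedgehog, Wnt, and BMP and TGF-beta genes had medians near 0 in epithelium, while FGF, dental follicle, collagen and mitochondrial genes were higher as lists. The Hedgehog, Wnt, and BMP and TGF-beta lists had medians of -0.03, -0.02 and -0.01, Notch 0.06 (-0.01 to 0.16, percentile 97.7) and FGF 0.10 (0.01 to 0.24, percentile 99.4), with no member past the 2-fold rule. In the FGF list Etv4, a target of FGF signalling, had 38 and 58.6 CPM, but it is a leading gene of the larger sub-cluster 6. The list's summed level was 1497 and 1482 CPM. Stratum intermedium and stellate reticulum genes had a median of -0.08, adhesion genes 0.03 and dental transcription factors 0.10. Of 14 keratins, 13 lay below 0 (median -0.14), among them Krt5 with 1079 and 875 CPM. Of 27 collagen and matrix genes, 18 lay above 0 and 1 passed the rule (median 0.12, 0.06 to 0.24, percentile 100), and the dental follicle list, with 7 measured members, had a median of 0.31 (0.11 to 0.55, percentile 100). Both hold genes of mesenchyme, as does sub-cluster 6 of this class. Dentin genes had a median of -0.07. Medians were 0.04 for hypoxia and glycolysis, 0.09 for interferon response, 0.03 for apoptosis and p53, and 0.12 for osteoclast-directed signals and vessels. Ribosomal protein genes stood at 0.05, mitochondrial genes at 0.24 (percentile 100) and sex-linked genes at -0.70.

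Immediate early genes, which tissue dissociation can switch on, were higher in both main classes. In epithelium 22 of 23 lay above 0, with a median of 0.56 (0.51 to 0.71) and 3 past the 2-fold rule. Egr1 had 350 and 626 CPM, and Jun 213 and 360 CPM. In mesenchyme 22 of 23 lay above 0, with a median of 0.55 (0.51 to 0.56) and 0 past the rule, and Fos had 2114 and 2793 CPM. The percentile was 100 in both classes.

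**Figure D2:**
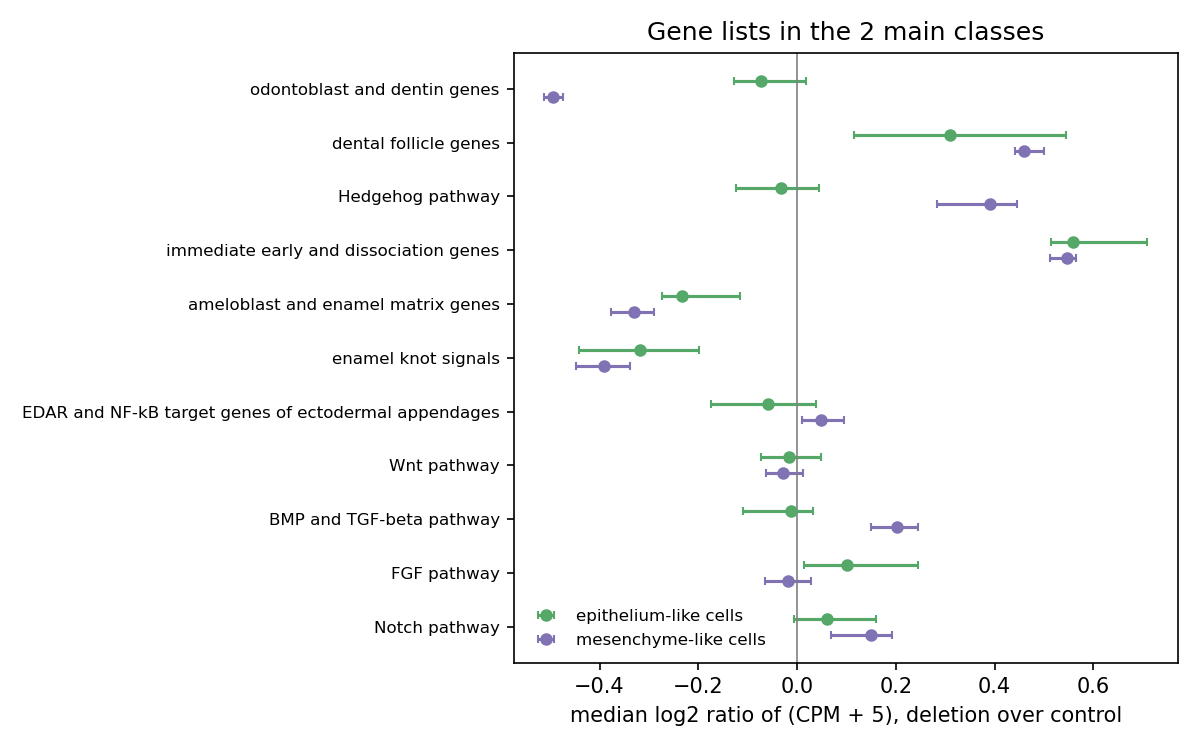
Median log2 ratio of (CPM + 5), deletion over control, of 11 gene lists in epithelium-like (green) and mesenchyme-like (purple) cells, with 95% resampling intervals that cover counting error only. In mesenchyme the dentin list stood at -0.49 and the Hedgehog list at 0.39, and immediate early genes stood at 0.56 and 0.55 in epithelium and mesenchyme.

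The share of cycling epithelium-like cells differed by a few percentage points, in opposite directions with and without thinning. After thinning, 46.8% of control cells (944 of 2015) and 50.3% of deletion cells (773 of 1537) held at least 2 UMIs of G2 and M phase genes, a difference of 3.44 percentage points with an interval from -1.29 to 8.17. Without thinning the shares were 62.1% and 59.5%, and the difference turned to -2.55 points (-6.81 to 1.70). The G2 and M phase list had a median of -0.12 in epithelium with 19 of 26 members below 0, while Mki67 had 130 and 149 CPM. The S phase list had a median of 0.09. In mesenchyme the thinned shares were 28.0% and 32.3% and the unthinned ones 50.3% and 46.5%, with list medians of 0.27 for G2 and M phase and 0.18 for S phase. Thinned odontoblast-like cells rarely counted as cycling (3.60% and 5.15%) and were 23.1% of thinned mesenchyme-like cells in the control and 10.3% with the deletion. Their smaller part therefore raises the thinned share of the class. The shares were 27.9% and 27.8% in follicle-like and 47.9% and 52.0% in papilla-like cells. They were 21.6% and 18.4% in osteoblast-like and 12.3% and 18.8% in perivascular or fibroblast-like cells. Free RNA can add to such calls, so no rate of division is read from them.

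Genes of dentin and its odontoblasts were lower in the mesenchyme-like cells of the deletion library, and odontoblast-like cells were a smaller part of them. Of 3415 genes at the minimum level, 15 were higher and 7 lower. In other settings between 1 and 21 were higher and between 0 and 11 lower. Of 16 measured dentin genes, 13 lay below 0 and 4 passed the rule, with a median of -0.49 (-0.51 to -0.47, percentile 0.00). Dspp, which encodes the main non-collagenous dentin proteins (chromosome 5, 104170712 to 104180127), had 1639 CPM in the control (interval 1627 to 1650) and 504 CPM in the deletion library (497 to 511). Dmp1, a matrix phosphoprotein gene (chromosome 5, 104202613 to 104214102), had 862 and 330 CPM, and Phex, a peptidase gene of phosphate metabolism, 309 and 137 CPM. Bglap had 253 and 99.5 CPM and Bglap2 160 and 75.0 CPM, but these osteocalcin genes are near-identical copies whose counts are uncertain. Col11a2 had 164 and 59.8 CPM and Cgref1 106 and 48.9 CPM. All 7 lower genes lead the largest odontoblast-like sub-cluster. Col1a1, the most abundant member of the list, had a log2 ratio of -0.66, whereas Ibsp had 411 and 569 CPM. Free RNA of Dspp also differed, with 48.7 and 8.03 CPM in endothelium-like cells.

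Odontoblast-like cells were 26.6% of control mesenchyme-like cells (2126 of 7991, interval 25.6 to 27.6%) and 12.8% of those with the deletion (1232 of 9595, 12.2 to 13.5%), when clustered without dentin genes and the leading odontoblast genes. With these 34 genes in place the shares were 22.7% and 9.79%. The clusters counted without them held 98.5% of the cells named odontoblast-like with them in place. The former share is therefore not independent of that naming. Dental follicle-like cells, from which the tissue around the tooth forms, were 22.9% (22.0 to 23.8%) and 34.9% (33.9 to 35.8%), and osteoblast-like cells 2.63% and 3.93%. Within odontoblast-like cells 1 gene was higher, Xist, and 1 lower, Lratd1. Dspp there had 4784 and 3096 CPM, and the dentin list a median of -0.14 (-0.20 to -0.09). With each sub-cluster given equal weight in both libraries, the list's median in mesenchyme was -0.10, with 1 gene higher and 0 lower by the rule. The largest clusters of the mesenchyme-like class were 4, 0 and 17 in the control and 17, 16 and 4 in the deletion library. With cells thinned to 1900 UMIs before sub-clustering, a setting chosen after the data were seen, odontoblast-like cells were 21.8% and 9.78%, follicle-like cells 23.0% and 35.2%, and osteoblast-like cells 2.52% and 3.51%. Digestion, sieving, red-cell lysis and dead-cell removal can set these shares too.

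**Figure D3:**
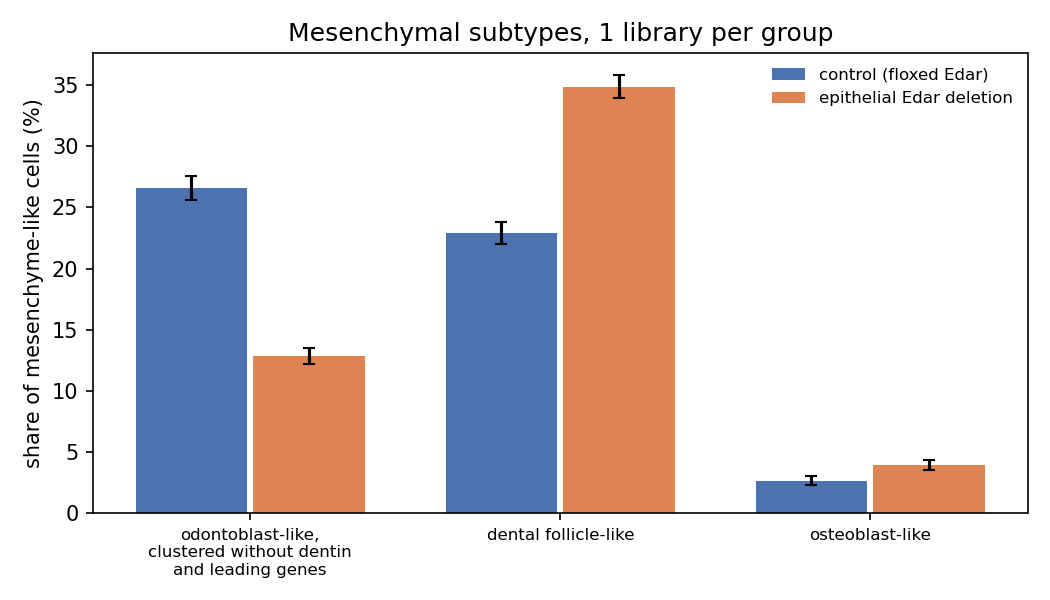
Share of mesenchyme-like cells (percent) that were odontoblast-like, dental follicle-like or osteoblast-like in the control (blue) and Edar deletion (orange) library, with exact 95% binomial intervals as error bars. Odontoblast-like cells, clustered without dentin and leading genes, were 26.6% and 12.8%, and dental follicle-like cells 22.9% and 34.9%.

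Pappa2, Cxcl1, Errfi1 and Csrnp1 had the largest ratios among the genes higher in the mesenchyme of the deletion library, and dental follicle genes were higher there as a list. Pappa2, a protease that frees insulin-like growth factors, had 88.2 CPM in the control (interval 85.6 to 91.0) and 282 CPM in the deletion library (277 to 288), the largest log2 ratio at 1.62. The proteases Mmp13 and Adamts1 had 121 and 255 CPM and 152 and 318 CPM. The chemokine gene Cxcl1 had 23.5 and 72.4 CPM, and the regulators Errfi1, Csrnp1 and Trib1 had 41.2 and 107 CPM, 89.5 and 221 CPM, and 35.1 and 77.7 CPM. The transcription factor genes Cebpb and Cebpd had 61.5 and 131 CPM and 68.6 and 144 CPM. Smim3 had 31.6 and 72.8 CPM, the neurotrophin receptor gene Ntrk2 39.9 and 87.2 CPM, and the basement membrane gene Frem2 57.8 and 121 CPM. Pappa2 and Ntrk2 lead a follicle-like sub-cluster and Mmp13 the osteoblast-like one. All 13 follicle genes lay above 0 (median 0.46, percentile 100), with Postn at 515 and 830 CPM and Igfbp5 at 3108 and 4799 CPM. With equal sub-cluster weights the follicle median turned to -0.08 and Postn to -0.21. Under median-of-ratios scaling 6 genes were higher and 7 lower.

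Hedgehog pathway genes, read in mesenchyme because epithelial Shh signals to it, were higher together by a small amount. All 11 measured members lay above 0, none past the 2-fold rule, with a median of 0.39 (0.28 to 0.45, percentile 99.98). The receptor and target Ptch1 had 429 and 521 CPM, the target Gli1 84.8 and 117 CPM, the antagonist Hhip 111 and 195 CPM and the co-receptor Gas1 70.4 and 120 CPM. With equal sub-cluster weights the median was 0.10. Other medians in mesenchyme were -0.03 for Wnt, 0.20 for BMP and TGF-beta, -0.02 for FGF, 0.15 for Notch and 0.20 for dental transcription factors, among which Pax9 had 86.6 and 115 CPM. They were 0.05 for EDAR targets, 0.10 for EDAR pathway members, 0.15 for stratum intermedium and stellate reticulum genes, 0.23 for adhesion and 0.20 for collagens and matrix. They were 0.31 for osteoclast-directed signals and vessels, 0.35 for interferon response, 0.26 for apoptosis and p53, and -0.05 for hypoxia and glycolysis. Sex-linked genes stood at -0.23, haemoglobin genes at -0.26, ribosomal protein genes at 0.02 and mitochondrial genes at -0.08.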

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

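The tests of the odontoblast-like share, of depth and dissociation for immediate early genes, and of free RNA and oral keratinocytes for Mt1 were chosen only after the result was seen, whereas those within cells of 1 sex for immediate early genes and Mt1 were set before. All tests within cells of 1 sex used fewer cells than all kept ones with Xist or Y-linked UMIs only.

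Odontoblast-like cells were fewer among the mesenchyme-like cells of the deletion library, at 22.7% in the control and 9.79% with the deletion (26.6 and 12.8% when clustered without dentin and leading genes). Lower depth is argued against, since the difference was -12.0 percentage points (interval -13.6 to -10.5) with cells thinned to equal depth before sub-clustering and naming, although the mesenchyme-like class itself was named at full depth. Within 1209 control and 2560 deletion cells with Xist and no Y-linked UMI it was -6.58 points (-9.87 to -3.38). Within 1613 and 1375 cells with a Y-linked UMI and no Xist it was -12.0 points. Both values argue against a different mix of sexes as the whole cause. Over all kept mesenchyme-like cells with Xist and no Y-linked UMI, 346 of 1658 in the control and 362 of 3420 with the deletion were odontoblast-like. More surrounding tissue taken with the germ would leave the odontoblast-like share of odontoblast-like and papilla-like cells alike, but it differed by -15.9 points (-18.4 to -13.3), although 2 leading genes of 1 papilla-like sub-cluster, Ecel1 and Gldn, also differed. A delay of odontoblast formation after Edar loss may be the cause, as may a lower yield of these cells in digestion or an earlier stage of the pups, and none of these was tested.

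Immediate early genes were higher in the deletion library, with medians of 0.56 in epithelium and 0.55 in mesenchyme. The difference was not smaller at equal depth, where the smaller of these medians was 0.60. A harsher or longer dissociation could account for it, since the medians were also above 0 in endothelium-like (0.35) and mural-like cells (0.54), but that in macrophage-like cells was 0.11 and that in neutrophil-like cells -0.08 (-0.27 to 0.05). In epithelium the median was 0.31 (0.18 to 0.45) within 438 control and 147 deletion cells with a Y-linked UMI and no Xist. It was 1.25 (0.97 to 1.34) within 295 and 645 cells with Xist and no Y-linked UMI, against 0.55 and 0.56 in mesenchyme. Each lay above 0 with its interval. By the rule set in advance, a different mix of sexes was argued against only if every one of these medians passed a fixed bound. The smallest, 0.31, lay just above that bound with an interval reaching below it, so the test cannot tell. The medians in mesenchyme lay above the bound with their intervals. The epithelial medians differed between the sexes, so a part played by the mix stays open there. A response to Edar loss was not tested apart from handling, since each group had 1 library.

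Mt1 was higher in epithelium-like cells of the deletion library, with a log2 ratio of 2.45. Free RNA would raise it alike in all classes, yet the log2 ratio in mesenchyme-like cells was 0.26 (961 and 991 UMIs), although glia-like cells too had more, at 77.6 and 338 CPM. It was 1.59 (1.02 to 2.08) in 438 control and 147 deletion epithelium-like cells with a Y-linked UMI and no Xist. In 295 and 645 such cells with Xist and no Y-linked UMI it was 2.46 (2.07 to 2.91). Both values argue against the mix of sexes as the whole cause. Without oral keratinocyte-like cells, which had the highest Mt1 level of the named epithelial subtypes in the control, the log2 ratio was 3.16, against a larger share of them as the cause. Metal or stress exposure of 1 litter or of 1 dissociation, and an effect of Edar loss, may each account for it and were not tested.

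The G2 and M phase list differed between the main classes, with a median in epithelium minus that in mesenchyme of -0.39, as it stood at -0.12 in the former and 0.27 in the latter. Mitochondrial genes also went opposite ways, with a difference of 0.32 between 0.24 in epithelium and -0.08 in mesenchyme. Neither difference between classes was tested. The smaller part of odontoblast-like cells, which rarely counted as cycling after thinning, can raise the mesenchymal side of the first. Unnamed cluster 5 took 9.20% of kept cells in the deletion library against 3.68% in the control. Among cells with Xist and no Y-linked UMI its share went the other way, with 217 of 2760 in the control and 151 of 5320 with the deletion. The larger share therefore lay in the other cells, and its cause was not tested.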

How the results depend on the processing

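The 12 results that answer a comparison were recomputed in 127 values, of which 95 stayed within the counting interval or within 1.5 times the count and 32 moved. None of the 127 turned a called direction. The 42 results on named genes, other lists and other shares gave 414 values, of which 216 stayed, 192 moved and 6 turned direction. Chosen only after the data were seen were the settings with cluster 5 added, without mesenchyme-led sub-clusters, without oral keratinocytes and with equal sub-cluster weights, and all settings of the odontoblast-like, follicle-like, osteoblast-like and mesenchyme-like shares, the follicle list and the immediate early list. No paired analysis was possible because each group had 1 library and the groups share only 1 replicate number. Depth limits genes near the minimum level, and the cause was not tested where a value moved, except where a setting removes cells or genes by construction.

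Under the stricter cell filter 5 genes were lower in epithelium and 11 in mesenchyme, EDAR targets stood at 0.058 (-0.06 to 0.15), dentin genes at -0.57 and the epithelium-like share at -6.79 points. Genes higher in mesenchyme numbered 9 without doublet removal, 9 with each library clustered on its own, 9 with classes from markers per cell, 6 in thinned cells, 6 under median-of-ratios scaling and 9 with cluster 5 added. Dentin genes stood at -0.54, -0.54, -0.53, -0.41, -0.55 and -0.54 in these 6 settings. Median-of-ratios scaling took out log2 shifts of -0.05 in epithelium and 0.05 in mesenchyme, which raised ratios in the former and lowered them in the latter. Thinning gave Edar -0.33, and cycling cells without thinning differed by -2.55 points. A pseudocount of 1 CPM gave 4 genes lower in epithelium and 0.46 for Hedgehog genes. With no minimum level 11 genes were lower in epithelium and 11 in mesenchyme, as more genes could be called, and dentin genes stood at -0.34.

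Equal sub-cluster weights gave 2 genes higher in epithelium, 1 higher and 0 lower in mesenchyme, and medians of -0.11 for enamel genes, 0.10 for Hedgehog genes and -0.10 for dentin genes. They turned the follicle list to -0.075, Postn to -0.21 and Amelx to 0.35, and Amelx was 0.061 without mesenchyme-led sub-clusters. By construction this setting removes differences in the makeup of a class, so these values depend on it. Without oral keratinocytes Idi2 turned to 0.10 and Calm4 to 0.27, both within counting error of 0. The odontoblast-like share differed by -7.55 points of all kept cells. It differed by -6.58 points in 1209 control and 2560 deletion cells with Xist and no Y-linked UMI, fewer than all kept ones. The mesenchyme-like share differed by 2.24 points at resolution 2, but by 9.97 points under the stricter filter, 8.03 without doublet removal, 8.13 with each library clustered on its own, 7.89 with classes from markers per cell and 8.15 with cluster 5 added.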

Other observations

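Interferon response genes were higher as a list in endothelium-like cells of the deletion library, in mesenchyme-like cells (median 0.35, 0.26 to 0.40) and in cluster 5 (0.32, 0.16 to 0.46). The chemokine gene Cxcl10, induced by interferon, had 116 CPM in control endothelium-like cells (interval 107 to 126) and 327 CPM in the deletion library (308 to 346), and 101 and 249 CPM in mural-like cells. Isg15, a ubiquitin-like interferon target, had 24.2 and 59.3 CPM in endothelium-like cells, where 14 of 18 interferon response genes lay above 0 (median 0.26, 0.17 to 0.35). The list's median was 0.09 (-0.07 to 0.20) in epithelium-like cells, 0.20 in mural-like cells, with an interval from -0.04 to 0.38 that includes 0, -0.00 (-0.05 to 0.08) in macrophage-like cells and -0.48 (-0.83 to -0.20) in neutrophil-like cells. Endothelium-like cells also had 228 and 480 CPM of Tiparp and 121 and 51.5 CPM of Depp1. In mural-like cells Eln, which encodes elastin, had 57.5 and 275 CPM, Plk2 26.5 and 75.2 CPM, and Neurl1b 54.5 and 22.3 CPM. Macrophage-like cells had less Hmox1, the haem-degrading enzyme gene, at 3083 and 1516 CPM, less Gpnmb at 1035 and 503 CPM, and less Ppbp at 74.7 and 18.1 CPM. A cluster led by Gpnmb and Hmox1 at resolution 2 held 88 and 38 of these cells, and without it the log2 ratios were -0.53 for Hmox1 (-0.62 to -0.44), 0.23 for Gpnmb (0.01 to 0.42) and -1.99 for Ppbp, a comparison chosen after the data were seen. Haemoglobin genes, which free RNA of red cells can bring, had medians of 5.16 in mural-like, 2.65 in endothelium-like and -0.49 in macrophage-like cells.

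Cluster 5, with mesenchymal markers but left unnamed, was led by Rspo4, Vit, Col8a2, Col9a2 and Frzb. By the rule 9 genes were higher and 18 lower in it. Klf10 had 19.9 and 55.8 CPM, Irgm1 40.9 and 104 CPM and Csrnp1 108 and 262 CPM. The transcription factor gene Tfap2b had 105 and 46 UMIs (log2 ratio -2.06), Foxp1 148 and 40.5 CPM, and the Wnt antagonist gene Dkk1 252 and 77.1 CPM. Dental mesenchyme transcription factors had a median of -0.32 (-0.44 to -0.24), with 15 of 17 below 0, but mitochondrial genes stood as low at -0.33 (12 of 13 below 0) and ribosomal protein genes at -0.11 (78 of 92 below 0). Among its cells with Xist only or Y-linked UMIs only, those with Xist were 63.8% in the control and 20.1% in the deletion library, whereas in epithelium-like cells they were 30.4% and 75.3% and in mesenchyme-like cells 33.8% and 60.2%. Over all kept cells, 20.8% and 34.9% held Xist and no Y-linked UMI, and 38.7% and 24.1% the reverse. These shares by sex were taken without thinning.

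Neutrophil-like cells, with only 137 and 136 cells, gave 270 genes higher and 101 lower by the rule, from only 277879 and 259845 UMIs. Ribosomal protein genes took 3.43% and 5.26% of these UMIs, and mitochondrial genes 1.91% and 2.82%. Mpo, a granule enzyme gene of immature neutrophils, had 1 and 90 UMIs (count ratio 16.8 to 3843), Postn 1 and 44, and E2f1 0 and 19. Mpo was also among the leading genes of unnamed cluster 18. Genes of other tissues were among those higher. All 27 collagen and matrix genes lay above 0 and 13 passed the rule (median 1.73, 1.34 to 2.08), the dental follicle list, which holds Postn, had a median of 1.61, and 43 counted genes were left unnamed because free RNA can bring them. Postn is therefore not read as a gene of the neutrophils themselves. Rgs1 had 29 and 0 UMIs, Il1a 15 and 2, and Saa3 14 and 2. In oral keratinocyte-like cells the cornified envelope genes Rptn and Sprr1b, chosen after their values were seen, had 225 and 178 UMIs in the control and 0 in the deletion library. In these cells 5 of the 10 leading genes were also 2-fold lower.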
